A study of Mus musculus with 2 samples.

How the data were processed

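Messenger RNA levels were measured on Affymetrix mouse 430A expression arrays in RAW264.7 cells, a mouse macrophage-like tumour line. Per the labels, cells received IFN-gamma at 1000 U/ml, or IFN-gamma at 1000 U/ml with adenosine at 300 uM, for 4 h. RNA from 2 experiments was pooled per treatment before hybridization, so each treatment is 1 array made from 1 pool. The spread between the pooled experiments cannot be recovered from such a pool, and no untreated array was analysed here.

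The deposited values are linear probe set intensity values, 1 per array for 22690 probe sets. The Affymetrix software GCOS is named in the submitters' processing notes. The signal algorithm and the scaling target are not given in the sources used here, and no detection calls were used. The deposited intensity values had not been brought to a common level. The mean over gene probe sets after leaving out the lowest and highest 2% was 263 on the IFN-gamma array and 89.5 on the adenosine array.

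Of the 22690 probe sets, 64 are manufacturer's controls and were kept for quality checks only. Among the other 22626, 20380 carried 1 gene symbol in the platform annotation, 691 carried several and 1555 had no name in the table used here. Gene symbols were checked through Entrez identifiers against RefSeq tables of GRCm38.p6. No coordinates are given, since no build is named for the values. Probe sets with several symbols or none stayed out of gene results.

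The design fixed before the data were examined assumed values already scaled by the submitters, and used them as deposited. Because that assumption failed, the median centring listed beforehand as an alternative was made the main scaling instead, and counts on the values as deposited are reported beside it. The log2 ratio of adenosine plus IFN-gamma over IFN-gamma was centred on its median over probe sets above the floor on both arrays. This median was -1.50, and signals of the adenosine array were accordingly multiplied by 2.82. All signals printed for that array are on this scale unless called deposited.

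A floor of 44.0, the 50th percentile of scaled gene probe set signals, was then applied. A gene whose brighter array was below it was not counted as measured. A dimmer signal below it was raised to it, and the resulting fold is given as "at least". The floor is a convention and not a measured detection limit. Each gene was read from its probe set with the highest mean over both arrays, which left 12393 genes, 6818 of them measured. The median log2 ratio of the measured genes was -0.08 after centring.

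With 1 array per treatment no test was possible and no p-value is given. Genes were counted by size, at 2-fold or more. A core of named genes was chosen by a rule fixed before the data were examined: the 10 highest and 10 lowest log2 ratios, the 3 largest absolute log2 ratios in each gene list, and 16 genes named whatever their value. Further members of gene lists were named as examples after their values had been seen. Among these, Adora2a and Adora2b were not analysed here. In all, 26 gene lists were fixed beforehand, 6 of them markers of other cell types, and 429 of their 489 entries were matched to a measured or unmeasured gene of the array. For each list with at least 5 measured members, the median log2 ratio was set against the medians of 10000 random lists of the same size, drawn with replacement from 20 bins of mean signal. A list outside the central 95% of these is said to stand apart, as a description of these 2 arrays. Percentiles were computed for 20 lists, of which chance alone would set apart 1 if the genes of a list varied independently.

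The spread of a single log2 ratio was estimated from 2375 genes with at least 2 probe sets above the floor on both arrays. The SD, from differences between the 2 brightest probe sets divided by the square root of 2, was 0.52 overall. In 4 groups of these genes by signal it was 0.55 in the dimmest and 0.40 in the brightest. It leaves out the spread between cultures and between arrays. The number of arrays limits the precision of every value below.

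The calculation was tested on simulated arrays with this scatter. Of 200 genes changed by 1.5 on the log2 scale 83.5% were recovered, and of 200 changed by 3 on that scale 96.0% were. Among the unchanged genes, 154 were counted as 2-fold higher and 210 as 2-fold lower in the first simulation, and 173 and 192 in the second. Of 200 unchanged lists, 5% stood apart in the first simulation and 7% in the second. These lists were random draws with independent scatter, for which about 5% is set by construction. They do not show how lists behave whose genes move together.

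Alternatives listed before the data were examined were floors at the 33rd and 67th percentiles, a pseudocount of 16 with no floor, quantile and loess scaling, the mean of all probe sets of a gene, leaving out probe sets with shared targets (names ending in _s_at, _x_at or _a_at), and thresholds of 1.5-fold and 3-fold. Scaling by trimmed means and by spiked-in controls was added after the data had been seen. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.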

Results

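Gene expression was compared in RAW264.7 macrophages after 4 h of IFN-gamma alone or of IFN-gamma with adenosine, a purine nucleoside that acts on cell-surface receptors. The study asked how adenosine changes the gene response of IFN-gamma-activated macrophages. Each treatment was represented by 1 array of RNA pooled from 2 experiments, so no difference below has a replicate check. Scatter between probe sets of the same gene, an SD of 0.52 on the log2 scale, is the only error available for a single log2 ratio.

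The adenosine array was dimmer over nearly its whole range. Its median signal was 15.2 against 45.9 on the IFN-gamma array, over 22626 gene probe sets. Control transcripts spiked into both hybridizations (18 probe sets) had a median log2 ratio of -0.53 ± 0.19 (SD over probe sets), against -1.50 for the genes. Spiked-in controls thus lay 0.97 ± 0.22 (SD) above genes of like signal on the log2 scale. Ratios of 3′ to 5′ signal, a measure of RNA integrity, were 1.19 and 1.12 for Actb on the IFN-gamma and adenosine arrays, 0.761 and 0.691 for Gapdh, and 1.86 and 2.06 for Tfrc. In the deposited values, with a floor of 24.5, 5605 of 7117 measured genes were at least 2-fold lower and 10 at least 2-fold higher with adenosine. All values that follow are relative to the array median, with the shift of -1.50 removed. The shift was smaller among the brightest genes. Genes of like signal to controls at 364 and 7577 on the IFN-gamma array had deposited medians of -1.66 and -0.90. The brightest genes therefore tended to lie above 0 on this scale. A gene with both signals above the floor and a ratio above 1 but below 2.82-fold on this scale had a lower deposited signal on the adenosine array.

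**Figure D1:**
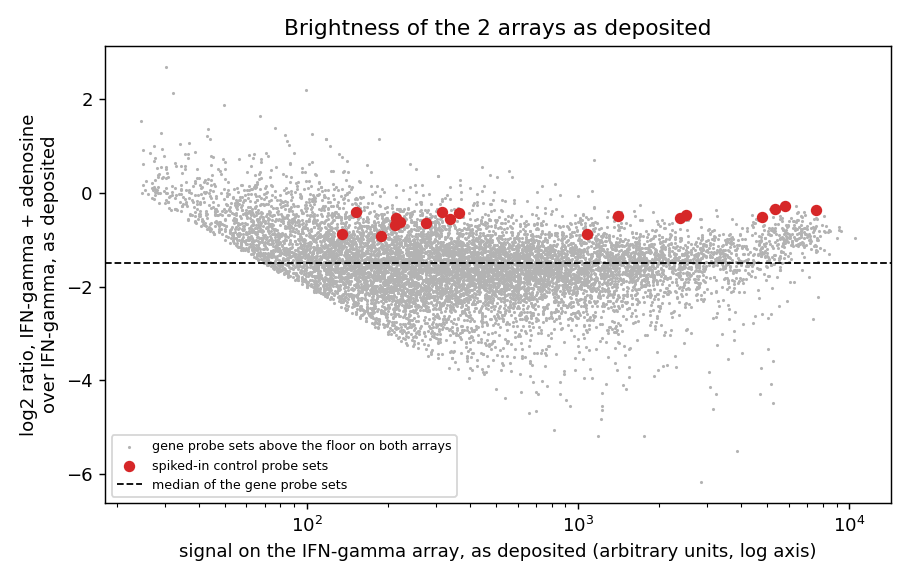
Log2 ratio of deposited signals (adenosine plus IFN-gamma over IFN-gamma, y axis) against the deposited signal on the IFN-gamma array (arbitrary units, log x axis). Each grey point is a gene probe set with a deposited signal of at least 24.5 on both arrays. The dashed line is their median of -1.50, and the 18 red spiked-in control probe sets have a median of -0.53.

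Relative to the array median, 691 genes were at least 2-fold lower and 308 at least 2-fold higher with adenosine, of 6818 measured. With signals below the floor raised to it, the lowest ratio belonged to Ptgs2, the inducible cyclooxygenase, with signals of 1054 on the IFN-gamma array and 58.6 on the adenosine array, a log2 ratio of -4.17. Gbp2, an interferon-induced GTPase, was 16.2-fold lower (3861 against 239). Rab43, a small GTPase, was at least 13.6-fold lower, and Cd40, a costimulatory receptor, was 12.8-fold lower. Ltb, which encodes lymphotoxin beta, was 11.9-fold lower and Rgs1, a regulator of G-protein signalling, 11.8-fold lower. Slfn8, of the Schlafen family, was at least 10.7-fold lower. The transcription factor gene Mitf, Krcc1 and the uridine phosphorylase gene Upp1 were 9.22-fold, 8.96-fold and 8.90-fold lower. Second probe sets gave log2 ratios of -4.68 for Gbp2, -4.30 for Cd40, -2.54 for Ptgs2, -1.03 for Mitf and -0.67 for Rab43.

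At the other end, Il1b, the interleukin 1 beta gene, was below the floor with IFN-gamma alone (30.4) and at 551 with adenosine, at least 12.5-fold higher. Fosl2, an AP-1 subunit, was 10.3-fold higher, from an IFN-gamma signal of 49.6, close to the floor. Bcat2, the mitochondrial branched-chain aminotransferase, was at least 7.14-fold higher, from a signal of 43.2, below the floor. Cytip was 6.25-fold higher, Tnfrsf11a, the receptor for the osteoclast factor RANKL, 6.21-fold higher, and the kinase gene Dmpk 6.19-fold higher. Rbm38, an RNA-binding protein gene, Ccnt1, the cyclin T1 gene, the zinc finger gene Maz and the stress-response gene Sesn2 were 5.03-fold, 5.00-fold, 4.85-fold and 4.71-fold higher. IFN-gamma signals were also low for Sesn2 (63.3), Ccnt1 (64.1), Maz (72) and Rbm38 (89.8). They were 118 for Cytip and Dmpk and 184 for Tnfrsf11a. Second probe sets gave log2 ratios of 3.12 for Cytip, 0.92 for both Tnfrsf11a and Sesn2, and 0.82 for Dmpk. No second probe set was measured for Il1b, Fosl2, Bcat2, Rbm38, Ccnt1 or Maz, so their folds rest on a single probe set.

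A second measured probe set was available for 286 of the lower genes, and 109 of these (38.1%) were also at least 2-fold lower by it. Among genes not counted as lower, 5.15% of second probe sets were. For the higher genes the corresponding number was 48 of 140 (34.3%), against 6.05%. Scatter between probe sets alone produced 154 higher and 210 lower genes in 1 simulation. It used the same shift for every gene and no spread between cultures or arrays. Its counts are therefore not an estimate of the false calls in these data.

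**Figure D2:**
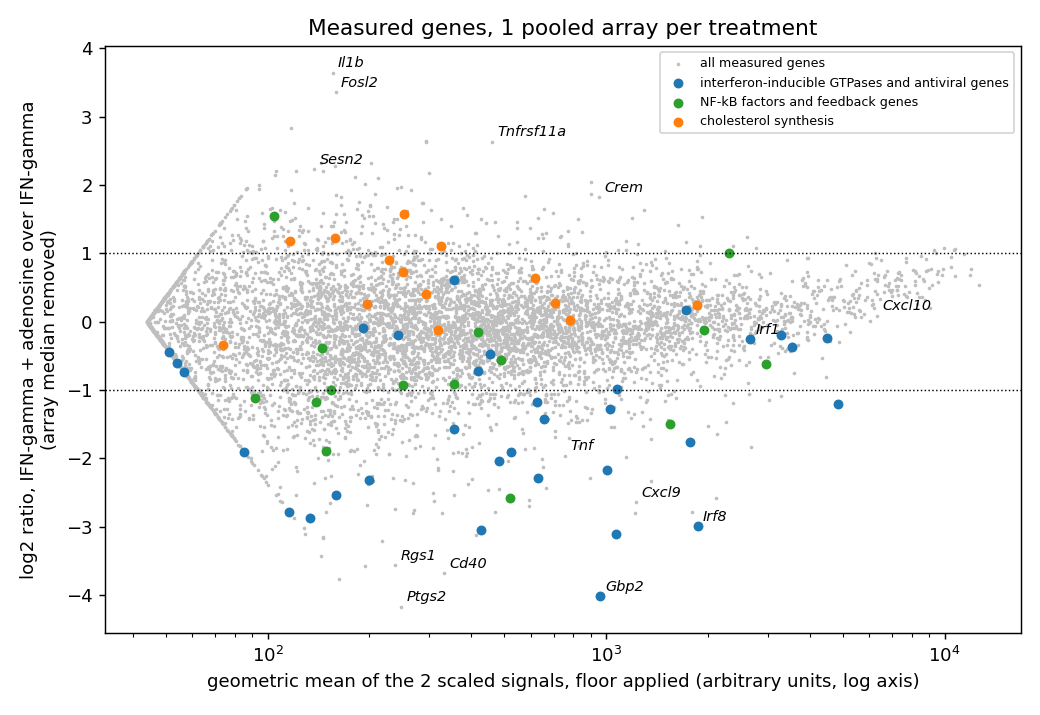
Log2 ratio relative to the array median (y axis) against the geometric mean of both scaled signals (arbitrary units, log x axis) for 6818 measured genes, with dotted lines at 2-fold. Most interferon-inducible genes (blue) and NF-kB genes (green) lie below 0, and 12 of the 14 cholesterol synthesis genes (orange) lie above 0, a direction that turns in the values as deposited (median -0.97) and with spiked-in scaling (median -0.44).

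Interferon-inducible GTPases and antiviral genes were lower as a group. Of 33 measured members, 19 were at least 2-fold lower, none was 2-fold higher, and 31 were below 0. Their median log2 ratio was -1.27, below all 10000 random lists of like signal (central 95% from -0.25 to 0.19). With signals below the floor raised to it, the largest differences after Gbp2 were in Gbp7 and Parp14. Gbp7, another GTPase of the family, was 8.64-fold lower (3155 against 365), and Parp14, a macrodomain ADP-ribosyltransferase, 8.28-fold lower. Irf8, a transcription factor of the macrophage lineage, went from 5262 to 660 (log2 ratio -2.99). Several abundant members differed little from the array median. Irf1, an early IFN-gamma target, was at 2904 and 2440 (log2 ratio -0.25). Ifi47 had a log2 ratio of -0.23, Irgm1 -0.20 and Igtp -0.37. Genes of like signal to a control at 4788 had a deposited median of -1.20, against the -1.50 removed. Against genes that bright, Ifi47 (4862 on the IFN-gamma array) therefore lay lower than its log2 ratio shows.

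Chemokines and cytokines induced by IFN-gamma were lower in 6 of 8 measured members, by at least 2-fold, with a list median of -1.44 that also lay below every random list. Cxcl9, a ligand of CXCR3, a chemokine receptor of T cells, was 6.24-fold lower (3065 against 491). The monocyte chemokine gene Ccl12 was 5.04-fold lower, and Cxcl11, which shares the receptor of Cxcl9, 3.55-fold lower (second probe set -1.10). Cxcl10, the other ligand of that receptor, was at 6136 and 6521, a log2 ratio of 0.09. Genes of like signal to a control at 5787 had a deposited median of -1.02, against the -1.50 removed. Genes that bright thus tended to lie above 0 here. Il18 and Il15 had log2 ratios of -1.59 and -1.29.

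NF-kB factors and feedback genes had a median log2 ratio of -0.91 over 15 members, below the random range of -0.45 to 0.28. At least 2-fold lower were 6 of them, and 2 were at least 2-fold higher. Birc3, an inhibitor of apoptosis, was 5.99-fold lower, and Tnfaip3, which encodes the ubiquitin-editing enzyme A20, 3.72-fold lower. Rel, the c-Rel subunit, was 2.92-fold higher, from a low signal of 61.2.

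The list of inflammatory cytokines and CC chemokines stood apart narrowly, with a median of -0.37 against a random range of -0.37 to 0.30 and a percentile of 2.21. It held members at both extremes. Besides Ptgs2, Tnf was 3.90-fold lower (1491 against 383) and the chemokine gene Ccl3 had a log2 ratio of -1.60, whereas Il1b and the neutrophil chemokine gene Cxcl2 (log2 ratio 1.27, lower than IFN-gamma alone in the deposited values) were higher. With trimmed mean scaling, added after the data had been seen, this list no longer stood apart (percentile 2.71).

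Genes of MHC class I presentation had a median log2 ratio of -0.39 over 12 members (random range -0.23 to 0.36), and 3 were at least 2-fold lower. These were the peptide transporter genes Tap1 (3.64-fold lower) and Tap2 (2.15-fold lower) and the tapasin-like gene Tapbpl (2.38-fold lower). The class I heavy chain genes H2-K1 and H2-D1 lay on the other side, at 0.93 and 0.83, although their probe sets share much sequence with other family members and both ratios turn negative in the values as deposited. Averaging all probe sets of a gene moved the list median to -0.28, inside its random range.

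MHC class II presentation and costimulation did not stand apart (median -0.32, 7 measured members), but it did on the lower side with the floor at the 33rd percentile (-0.79) and with the pseudocount (-0.66). Beside Cd40, Cd80 was 3.86-fold higher from a signal of 48.1, and Cd86 had a log2 ratio of -0.83. Ciita, the class II transactivator, was below the floor on both arrays, at 22.5 and 5.36.

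**Figure D3:**
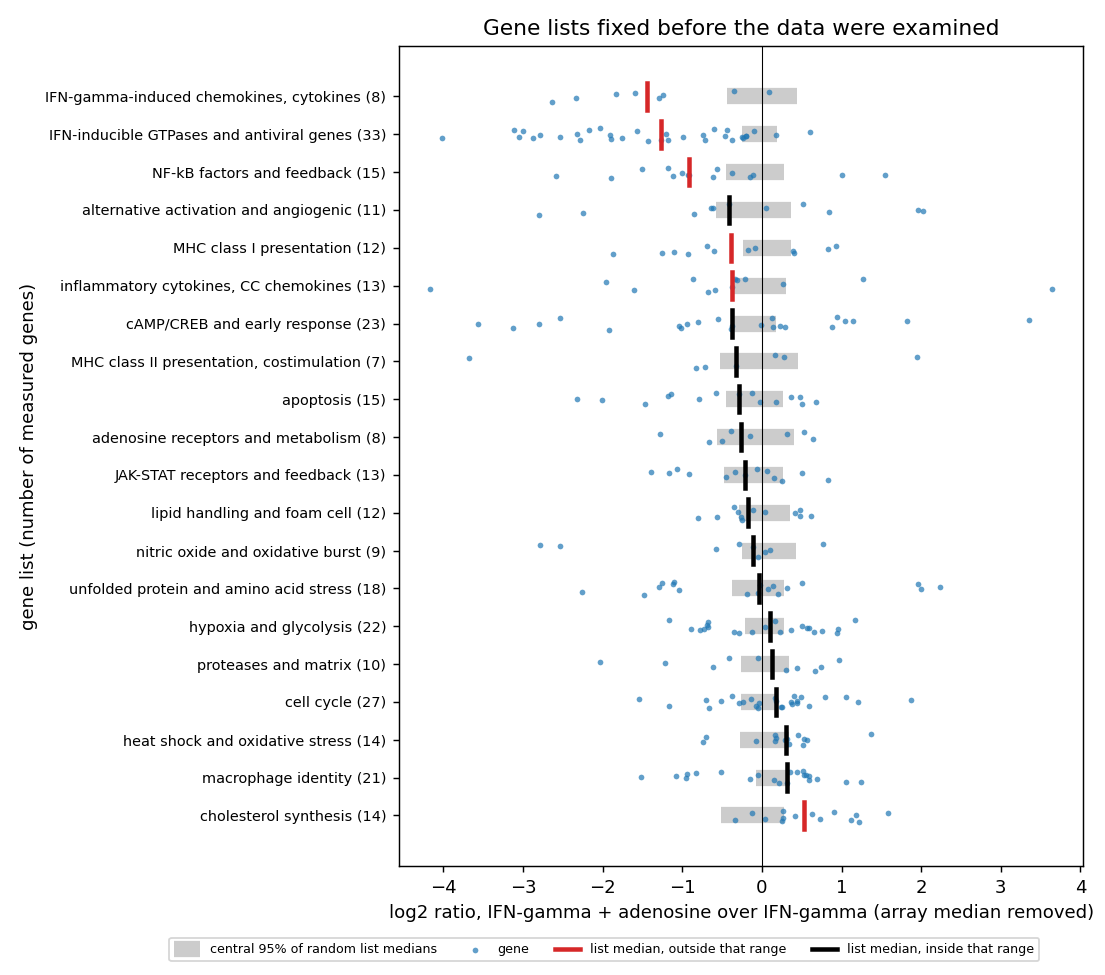
Log2 ratio relative to the array median (x axis) for the members (blue points) of the 20 gene lists with at least 5 measured genes (y axis, number measured in brackets), with each list's median (red or black bar) and the central 95% of medians of 10000 random lists of like signal (grey). In 5 lists the median lies below the grey range and in 1, cholesterol synthesis, above it, although the median of that list turns to -0.97 in the values as deposited and to -0.44 with spiked-in scaling.

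Cholesterol synthesis was the 1 list that stood apart on the higher side, with a median log2 ratio of 0.52 over 14 genes (random range -0.51 to 0.28), which became -0.97 in the values as deposited and -0.44 with spiked-in scaling while staying above its random range in both. At least 2-fold higher were 4 members and none was 2-fold lower. These counts became 0 and 7 in the values as deposited, and 0 and 2 with spiked-in scaling. With the mean of all probe sets they were 1 and 0. Stard4, a sterol transport protein gene, had a log2 ratio of 1.58, Dhcr7, the last enzyme of one branch of the pathway, was 2.33-fold higher and Mvd, of the mevalonate steps, 2.26-fold higher; Dhcr7 and Mvd had negative log2 ratios (-0.27 and -0.32) in the values as deposited. Second probe sets gave log2 ratios of 0.12 for Stard4 and 0.80 for Mvd. Without probe sets of shared targets the list median was 0.27 and no longer stood apart.

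Early response and cAMP-regulated genes went both ways. Of 23 measured, 7 were at least 2-fold lower and 4 at least 2-fold higher, with a median of -0.37 at percentile 3.31, inside the random range. The list stood apart on the lower side with loess scaling, with the floor at the 67th percentile and without shared probe sets, whereas its median turned to 0.03 with the pseudocount. Lower members were Rgs1, Rgs2 (8.73-fold), and the growth factor-induced genes Egr1, with a log2 ratio of -2.80, and Egr2, at least 5.82-fold. Crem, a cAMP-responsive repressor and activator gene, was 3.53-fold higher (506 against 1785), and its second probe set had a log2 ratio of 1.58. The nuclear receptor gene Nr4a1 was at 92.8 and 101.

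Genes linked to alternative activation and angiogenesis did not stand apart (median -0.42 over 11 genes, 0.05 with the floor at the 67th percentile and with the pseudocount). Il4ra, the interleukin 4 receptor alpha chain, was 4.06-fold higher, with a second probe set at 1.72. Vegfa, the angiogenic growth factor, was 3.91-fold higher by its brightest probe set, but a second probe set gave a log2 ratio of -0.12, so the direction turns when shared probe sets are left out. Pdgfb was 6.98-fold lower and Nrp1 at least 4.74-fold lower, but other probe sets gave smaller log2 ratios of -1.02 for Pdgfb and of -1.10 and -0.84 for Nrp1.

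In the nitric oxide and oxidative burst list (median -0.11 over 9 genes, not apart), Acod1, the itaconate-producing enzyme, was 6.90-fold lower (4702 against 682). Gch1, the first enzyme of tetrahydrobiopterin synthesis, was 5.78-fold lower (second probe set -1.63). Nos2, the inducible nitric oxide synthase, was below the floor on both arrays at 39.0 and 34.1.

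Receptors and feedback genes of JAK-STAT signalling did not stand apart (median -0.22 over 13 genes). Cish was 2.63-fold lower, the phosphatase gene Ptpn6 2.25-fold and Jak2 2.10-fold lower. Second probe sets of Ptpn6 (-0.69) and Jak2 (-0.87) were short of 2-fold. Socs1 and Socs3, feedback inhibitors of the pathway, had log2 ratios of 0.50 and -0.45. Both lay within the overall SD of probe set scatter, 0.52, of 0. That of Socs3 lay outside the SD of 0.40 of genes in its signal group, the brightest. Other Socs3 probe sets gave log2 ratios of -0.69 and 0.27. The Socs1 ratio turns negative in the values as deposited.

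Stress genes were split. In the unfolded protein and amino acid stress list (18 genes, median -0.04, not apart, turning to 0.01 without shared probe sets and 0.02 with trimmed mean scaling), 7 genes were at least 2-fold lower, among them Chac1 (at least 4.79-fold), and Ddit3 and Atf4 with log2 ratios of -1.48 and -1.10. Sesn2, the cystine transporter gene Slc7a11 (3.99-fold) and Ddit4 (log2 ratio 1.96) were higher. In the apoptosis list (15 genes, median -0.29, not apart), 5 were at least 2-fold lower and none 2-fold higher. These included the death receptor gene Fas (5.02-fold), Bid (4.01-fold, second probe set -1.24) and Casp1 (2.78-fold). Among proteases, the urokinase gene Plau was 4.11-fold (second probe set -1.69) and its receptor gene Plaur 2.33-fold lower. Mmp9 was below the floor on both arrays.

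The remaining lists did not stand apart with the main scaling and floor. Their medians were 0.18 for the cell cycle (27 genes), 0.10 for hypoxia and glycolysis (22), 0.12 for proteases and matrix (10), 0.30 for heat shock and oxidative stress (14), -0.18 for lipid handling (12), 0.31 for macrophage identity (21) and -0.27 for adenosine receptors and metabolism (8), and the 4 medians from 0.10 to 0.30 and that of 0.31 turn negative in the values as deposited and with spiked-in scaling. The protease median also turned with loess scaling (-0.14) and without shared probe sets (-0.05), and the hypoxia median without shared probe sets (-0.23). The adenosine list turned to 0.08 and 0.31 with the floors at the 33rd and 67th percentiles and to 0.31 with the pseudocount. Under single alternatives some of these lists stood apart: the cell cycle higher with quantile and loess scaling, heat shock higher with quantile scaling, macrophage identity higher without shared probe sets, and lipid handling lower with the floor at the 33rd percentile. Examples were Ccnd2 (2.91-fold lower, as were 2 of 4 other probe sets by at least 2-fold), the replication licensing gene Cdc6 (3.66-fold higher), and the Fc receptor gene Fcgr1 (2.87-fold lower). Adora2a and Adora2b, which encode adenosine receptors, were not analysed here.

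Markers of other cell types were nearly all below the floor. None of the 16 markers of fibroblasts, endothelium and epithelium, of the 11 of granulocytes and mast cells, or of the 5 of erythroid cells was measured. Of 11 T and B cell markers, Ighm (658 against 275) and Zap70 (45.9 against 97.0) were, and of 8 dendritic cell markers Fscn1 was (34.7 against 57.8). Among 8 osteoclast markers, Tnfrsf11a and Nfatc1 (2.46-fold, with a second probe set at 2.18) were higher, and Ocstamp was at least 2.13-fold lower; Nfatc1 and Zap70 turn negative in the values as deposited.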

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

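No paired analysis was possible because each treatment has 1 array, and no replicate could be left out. Scaling decides the split of the 2-fold counts. Each count is of the genes measured under its setting, 6818 with the main one, 7117 as deposited and 6975 with spiked-in scaling. Against 308 higher and 691 lower genes (69.2% of them lower), the values as deposited gave 10 and 5605 (99.8% lower) and spiked-in scaling, added after the data had been seen, 33 and 3538 (99.1%). Quantile scaling gave 398 and 568 (58.8%), with 301 and 567 genes shared with the main counts. The floor at the 33rd percentile gave 599 higher genes and 944 lower of 9177 measured, and the floor at the 67th gave 133 and 328 of 5062. A 1.5-fold threshold gave 879 and 1489, a 3-fold threshold 67 and 202. Other settings stayed within 1.5 times of both counts.

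The lists of interferon-inducible genes, IFN-gamma-induced chemokines and NF-kB genes stood apart on the lower side under all 10 alternatives. Their medians ranged from -2.75 to -1.19, from -2.79 to -0.85 and from -2.41 to -0.56. MHC class I presentation lost this when all probe sets were averaged (-0.28), inflammatory cytokines with trimmed mean scaling (-0.31), and cholesterol synthesis without shared probe sets (0.27). The cholesterol median turned negative as deposited (-0.97) and with spiked-in scaling (-0.44). Lists that did not stand apart did so in 10 list and setting combinations, among them early response genes in 3 and MHC class II presentation in 2, the floor at the 33rd percentile (-0.79) and the pseudocount (-0.66). Among genes named by the fixed rule, those at least 2-fold apart whose direction turned in the values as deposited were Dhcr7 (-0.27), Dnajb1 (-0.13), E2f1 (-0.28), Laptm5 (-1.90), Mvd (-0.32), Nfatc1 (-0.19), Pfkl (-0.33) and Zap70 (-0.42), all by the uniform shift except Laptm5, which was then read from another probe set. Vegfa turned without shared probe sets (-0.12), which leaves its second probe set alone. Where no construction shows it, the cause was not tested. Genes under the floor of 44.0 could not be ordered.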

Other observations

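Lists in this part were written after gene values had been seen. The tests of second probe sets and of unseen p53 targets were chosen before their results were seen. The tests of the dimmer array, of brightness and of saturation were chosen afterwards, with the bounds for the dimmer array set when its values were known. Genes responsive to type I interferon (13 measured, among them Ifit2, Oasl2, Rsad2 and Usp18) had a median log2 ratio of -1.56, with 8 at least 2-fold lower and 12 below 0. The IFN-gamma-inducible GTPases of the GBP and IRG families (10 measured) had a median of -1.09, with 5 at least 2-fold lower and all 10 below 0. Both lists are subsets of the list fixed beforehand, and both lay below their random ranges under all 10 alternatives. The difference between them was not tested. In the Schlafen family, Slfn8 (at least 10.7-fold), Slfn4 (log2 ratio -1.53) and Slfn2 (-0.77) were lower, while Slfn3 was near the floor. Of the 4 measured members, 3 were below 0 and 1 above 0. With the floor at the 33rd percentile 5 were measured, 2 at least 2-fold lower and 1 at least 2-fold higher.

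Cytosolic ribosomal protein genes (41 measured) had a median log2 ratio of 0.53, above the random range of 0.07 to 0.37, and turned negative with the values as deposited and with spiked-in scaling. They stood apart under 7 of 10 alternatives, but not with quantile scaling (median -0.04), with loess scaling (0.02) or without shared probe sets (0.36). Both of these scalings remove differences that depend on brightness. Mitochondrial ribosomal proteins (74 genes, median -0.12), oxidative phosphorylation (71, median 0.16), the proteasome (38, median 0.02), lysosomal genes (20, median 0.02) and MAP kinase feedback genes (9, median 0.19) did not stand apart, except oxidative phosphorylation on the higher side with quantile scaling (percentile 97.8), and the 4 positive medians turn negative in the values as deposited and with spiked-in scaling. With some other settings the medians of the proteasome, lysosomal and MAP kinase feedback genes also turn.

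Among the genes with the highest ratios were Sesn2, Rbm38, Phlda3 and Gtse1, all known p53 targets, which led to the hypothesis that p53 targets are higher as a class with adenosine. Of further targets whose values had not been seen, 18 were measured. Their median log2 ratio was 0.39 (random range -0.49 to 0.23), with 4 at least 2-fold higher (Polk 3.16-fold, Mdm2 3.11-fold, Trp53inp1 at least 2.72-fold and Tob1 2.48-fold) and 2 at least 2-fold lower (Btg2 and Rrm2b). Cdkn1a, a main p53 target, had a log2 ratio of -0.08, and Fas one of -2.33. The unseen targets stood above the random range under 8 of 10 alternatives, but not with loess scaling (median -0.07, percentile 79.3) or with a pseudocount and no floor (percentile 93.9). The cause of these losses was not tested, the median turns negative in the values as deposited and with spiked-in scaling, and the hypothesis stays open.

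The adenosine array was dimmer, with a median log2 ratio of -1.50. A lower scanner gain or weaker stain over the whole array would lower the spiked-in controls as much as genes of like signal. They lay 0.97 ± 0.22 (SD over probe sets) above those genes. This comparison assumes the same amount of controls on both arrays, as the manufacturer's protocol sets. The SD leaves out error in that amount. Degraded RNA was taken to raise 3′ over 5′ signal by 1 or more on the log2 scale, with less than 0.5 counting against it. The change was -0.083 for Actb, -0.14 for Gapdh and 0.15 for Tfrc. The spiked-in controls themselves had a median log2 ratio of -0.53 ± 0.19 (SD over probe sets), so a share from gain or stain stays open. Also open is the gap between genes and spiked-in controls, a log2 difference of -0.97. The gene shift was not uniform, with medians of -1.66 and -0.90 for genes of like signal to controls at 364 and 7577. The 3′ signals of Actb, Gapdh and Tfrc had deposited log2 ratios of -0.62, -0.61 and -1.13. Why the shift depended on signal was not tested. Less labelled target on the array and fewer messenger RNAs per amount of total RNA in the adenosine pool cannot be told apart. Both would lower genes in general, and there is 1 pool per treatment.

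The lower interferon-inducible genes are a pattern for which adenosine treatment is the biological candidate explanation, untested here beyond 1 pool per treatment. Error of single probe sets is argued against by the second probe sets of 11 of these genes, which had a median log2 ratio of -1.34, below their random range of -0.45 to 0.42, with 9 of 11 below 0. A brightness-dependent difference between the arrays is argued against by loess scaling, under which the list median was -1.33. Saturation of bright probe sets as the reason why Irf1, Irgm1, Igtp and Ifi47 stayed near 0 is left open. At least 2-fold lower were 5 members as bright as Irf1, but probe sets may saturate at different signals. A difference between the pooled cultures unrelated to adenosine stays open.

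The 2-fold counts themselves may be partly scatter of dim or faulty probe sets. The second probe sets of higher genes were 2-fold higher 4.59 times as often as second probe sets of any gene, and those of lower genes 2-fold lower 4.45 times as often. Scatter alone was predicted to give no more than 2 times, and its absence at least 5 times, so both values fall between and leave open how much of each count is scatter.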
